A study of Mus musculus with 12 samples.

How the data were processed

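Polyadenylated RNA of mouse interscapular brown and posterior subcutaneous white adipose tissue was measured in 12 libraries, 2 for each of 3 genotypes (wild type, 1 copy and 2 copies of the Ucp1-CreEvdr transgene) in each tissue. Per the labels, the authors extracted RNA with Trizol and RNeasy columns and prepared libraries with a stranded mRNA kit. The deposited table held raw read counts per gene, made by the authors with STAR and featureCounts (Subread) on mouse build mm10. Versions, annotation, strand setting and any filter were not given. The values were whole numbers in 24541 rows, which included rows for Cre and loxP that the authors had added, and no normalization had been applied. Groups were taken from the genotype and tissue in the labels. Replicate numbers within a group were assigned here by the order of the samples, since the labels give library numbers only and do not say which depots came from the same mouse, nor the sex of the mice.

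Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9 for figures. Each tissue was fitted by itself with its 6 libraries and 3 genotypes (3 residual degrees of freedom). Genes were kept with filterByExpr on the groups in the fit, which left 13414 genes in brown and 15287 in white adipose. Counts were scaled with TMM factors, which ran from 0.9756 to 1.037 in brown and 0.9223 to 1.094 in white adipose. Differences were tested with edgeR's quasi-likelihood test (robust, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Common biological coefficients of variation were 0.148 and 0.159. Interactions between tissue and genotype, and the difference of wild type depots, came from 1 fit of all 12 libraries (15559 genes, 6 residual degrees of freedom, coefficient of variation 0.155, TMM factors 0.8042 to 1.313). CPM values were computed with the TMM factors of the fit. The SE of a log2 fold change was its size divided by the square root of the F statistic. Where all libraries of a group were at 0, a fold is given only as a bound, with that group at 3 counts over its libraries. Total counts per library ran from 15679884 to 31814056, and intervals and bounds cover counting error only.

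Before the data were examined, the comparisons, tests, alternatives, gene lists and the rule for named genes had been fixed. The rule named, for each comparison of a transgenic group with wild type in a tissue, Ucp1, Tbc1d9 and Elmod2. It added the 6 largest rises and 6 largest falls among genes that passed, had a mean log2 CPM of at least 1, did not overlap between the groups and carried a plain symbol, and up to 4 members of each list with the smallest adjusted p among those that passed. For 2 copies against 1 copy and for the interactions it named the 5 largest rises and 5 largest falls, and for wild type depots Ucp1, Cidea, Lep, Zic1 and Hoxc10. To limit length, of the list members in white adipose only the 2 with the smallest adjusted p for 2 copies are given (for the epithelial list, which had calls with 1 copy only, those of 1 copy), a choice made after the data were seen. The results of 3 genes taken by the rule are not reported here. The genes Cre and Dbp are given in further places because a figure or a test uses them.

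The 27 lists covered Ucp1 and its genomic neighbours, thermogenic brown adipocyte genes, nuclear-encoded and mitochondrially encoded respiratory chain genes, fatty acid oxidation, de novo lipogenesis, cholesterol biosynthesis, general adipocyte and adipocyte progenitor genes, the integrated stress response, the unfolded protein response, p53 and DNA damage, and the interferon response. They also covered macrophage, lymphocyte, skeletal muscle, mammary and other epithelial, extracellular matrix, endothelial, nerve and Schwann cell, cell cycle, circadian clock, immediate early and heat shock, futile cycle, glycolysis, blood and sex-linked genes. Lists were compared with all other genes by limma's camera with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. Lists with fewer than 3 tested genes were not tested as sets. For 2 copies against wild type, called genes were counted in windows of 5 Mb (hypergeometric test) and on chromosomes (one-sided Fisher's exact test), with positions from a mouse gene annotation. Of the table's rows 24458 were matched to a position and 83 were not.

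Alternatives were median-of-ratios scaling, the DESeq2 Wald test, no filter on low counts, a filter on a mean CPM of at least 1, leaving out each library in turn (the spread is then pooled, so a lone library is assumed to vary like the others), a fit of all 12 libraries, a test against a fold of 1.5 (glmTreat), and the mean of the skeletal muscle list (brown) or lymphocyte list (white) as a covariate. For lists and windows they were the estimated correlation, the thermogenic list without Ucp1, and windows of 2 and 10 Mb. After the data were seen, brown adipose counts were also made without muscle-marked genes, which were at least 8 times higher, and at 1 CPM or more, in white 1-copy replicate 1 than in its replicate and in white wild type. Overlap between doses was compared with 20 simulations of unchanged groups. With 2 libraries per group no outlier test and no refit with regrouped libraries was made.

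The test was checked on simulated data with 200 changed genes per run. Of genes changed by a fold of 1.5, 2 and 4 it recovered 13%, 75.3% and 88.4% in brown adipose, 7.41%, 67.9% and 84.6% in white adipose, and 0%, 30.7% and 80% for the interaction, and it called 9, 9 and 2 unchanged genes. Reads were not used here, so reads of the transgene's own Ucp1 sequences were not separated from those of the endogenous gene.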

Results

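Polyadenylated RNA was sequenced from 2 fat depots of mice that carried 0, 1 or 2 copies of the Ucp1-CreEvdr transgene. This transgene is a bacterial artificial chromosome in which Ucp1 regulatory sequences drive Cre recombinase, and it is used to delete floxed genes in brown and beige adipocytes. The depots were interscapular brown adipose tissue and the posterior subcutaneous (inguinal white) adipose tissue, called brown and white below. Mice were 6 weeks old, kept at room temperature on chow and killed in the morning. Each of the 6 groups held 2 libraries, 12 in all, and total counts ran from 15679884 to 31814056 per library. Nothing in the labels says that the 2 libraries of a group came from separate mice, so the p-values measure only the spread between these libraries, which may be technical. Correlations between the 2 libraries of a group ran from 0.981 to 0.994 on log2 CPM. Counts per gene differed between them by more than sampling noise in every group (chi-square per degree of freedom 9.07 to 41.5). Values below are CPM (counts scaled by library size with TMM factors within a tissue) as mean ± SD over the 2 libraries, log2 fold changes are given ± SE, and adjusted p-values come from edgeR's quasi-likelihood test. All 12 libraries had Xist, the transcript of the inactive X chromosome, at 304 to 1146 CPM of the library total, and reads from Y-linked genes were 0 except for a few in brown wild type replicate 2 (at most 0.157 CPM).

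The transgene itself was read from a row for Cre that the authors had added to the gene table. Cre reads were 0 in all 4 wild type libraries. In brown adipose they numbered 606 and 444 with 1 copy and 3243 and 1770 with 2 copies. These are 31.9 ± 8.39 CPM, at least 521-fold above wild type (adjusted p = 0.0485), for 1 copy. That call was lost without either wild type or either 1-copy brown library (adjusted p = 0.12, 0.106, 0.29 and 0.22). For 2 copies the level was at least 2288-fold above wild type, with an SD of 72.3 CPM, and the test was not passed (adjusted p = 0.0575). Both bounds set wild type at 3 counts over its 2 libraries. In white adipose the Cre row held 83 reads in 1 library with 1 copy and 0 in the other 3 transgenic libraries. The library with Cre reads was also the transgenic white library with the most Ucp1 reads (2400, against 28, 10 and 4). Per 1000 Ucp1 reads, Cre stood at 6.13, 5.92, 23.5 and 7.58 in the 4 transgenic brown libraries and at 34.6 in that white library, with an exact Poisson 95% interval of 27.6 to 42.9 that covers counting error only. With 28 Ucp1 reads or fewer, the 3 other white libraries do not exclude a ratio of that size (upper limits 131.7, 368.9 and 922.2). A row named for loxP held 0 counts in all 12 libraries.

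Ucp1 encodes the uncoupling protein that makes brown fat produce heat, and lies on chromosome 8 (mm10, 83290352 to 83298452) between Tbc1d9 (83165352 to 83272934) and Elmod2 (83312632 to 83332486). In brown adipose Ucp1 was at 6734 ± 1047 CPM in wild type, 5284 ± 1263 with 1 copy and 10180 ± 2730 with 2 copies, and none of these differences passed (adjusted p = 0.477 and 0.276 against wild type and 0.109 between the copy numbers). Tbc1d9, which encodes a protein with a Rab GTPase-activating domain, rose with each copy in brown adipose, from 8.59 ± 0.78 to 13.8 ± 0.59 and 29.1 ± 2.68 CPM. Its log2 fold changes were 0.68 ± 0.15 for 1 copy (adjusted p = 0.0449), 1.76 ± 0.15 for 2 copies (adjusted p = 0.00802) and 1.08 ± 0.14 for 2 copies against 1 copy (adjusted p = 0.0188). The call for 1 copy was lost without any single brown library except wild type replicate 2 (adjusted p = 0.0625 to 0.314). Elmod2, a regulator of Arf GTPases, went from 50.2 ± 21.5 to 72.9 ± 2.56 and 157 ± 3.71 CPM without passing (adjusted p = 0.349 and 0.071). In white adipose Tbc1d9 rose from 18.9 ± 3.62 to 28.7 ± 0.37 CPM with 1 copy (adjusted p = 0.0142) and to 34.7 ± 1.00 CPM with 2 copies (adjusted p = 0.00248), while 2 copies against 1 copy did not pass (adjusted p = 0.362). Elmod2 rose with 2 copies, from 63.3 ± 1.92 to 101 ± 17.3 CPM (adjusted p = 0.0103; 1 copy 82.4 ± 12.9 CPM, adjusted p = 0.0809). White Ucp1 was uneven within groups, at 123.2 ± 148.8 CPM in wild type, 54.9 ± 75.5 with 1 copy and 0.339 ± 0.239 with 2 copies, and did not pass (adjusted p = 0.635 and 0.0756). The transgenic white libraries also held lymphocyte transcripts that were near 0 in wild type, as described below. The white rises of Tbc1d9 and Elmod2 are therefore not separated from that tissue. Reads of an endogenous Ucp1 allele and of any Ucp1 sequence inside the transgene fall in the same row of the table and were not separated.

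**Figure D1:**
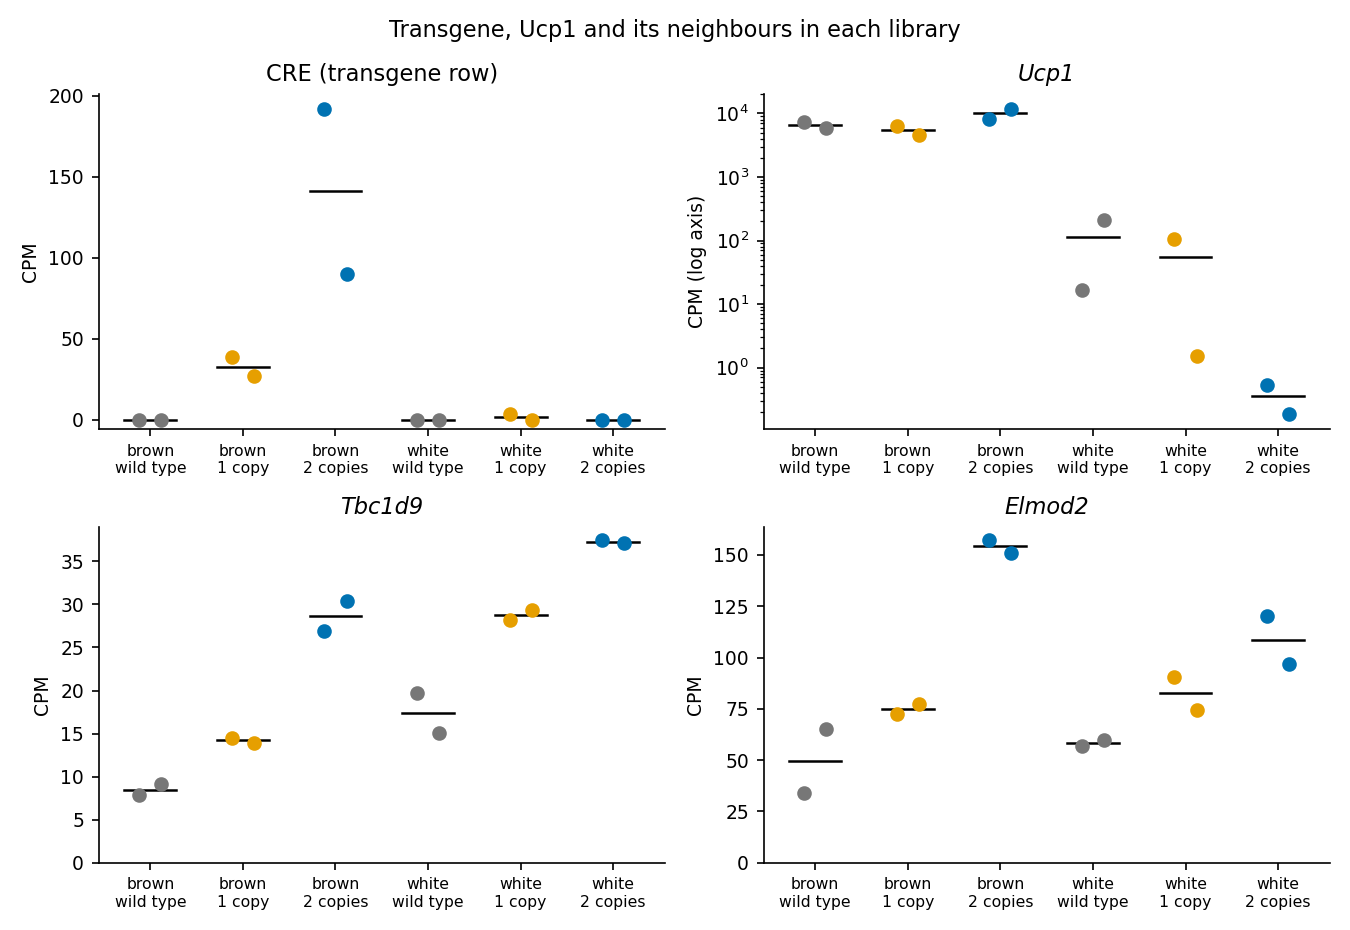
CPM of library totals (vertical axes, logarithmic for Ucp1) for Cre, Ucp1, Tbc1d9 and Elmod2 in each of the 12 libraries, by tissue and genotype, with points for libraries and lines for the means of 2. Means of Tbc1d9 lay higher with each copy in both tissues, though the step from 1 copy to 2 copies passed in brown adipose only, while Cre was at 0 in 3 of the 4 transgenic white libraries. White values are not separated from the lymphocyte transcripts that the transgenic white libraries held.

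Brown adipose with 1 copy was compared with wild type to see what a single dose of the transgene changes in the tissue where it is active. Genes of the circadian clock shifted together. Dbp, an output of the clock that cycles strongly, was at 70.7 ± 6.89 CPM against 3.68 ± 1.17 in wild type (log2 fold change 4.22 ± 0.20, adjusted p = 0.000446). Per3 (2.26 ± 0.27, adjusted p = 0.0162), Cry2 (1.57 ± 0.11, adjusted p = 0.00154) and Hlf (1.41 ± 0.11, adjusted p = 0.00229) rose, and Nfil3, a repressor that binds the same sites as Dbp, fell (-1.99 ± 0.11, adjusted p = 0.000519). Of 18 clock genes tested 8 rose and 2 fell, and 8 rose and 5 fell adjusted over the list alone. The list stood apart from other genes (adjusted p = 6.43e-07 with the preset correlation, adjusted p = 0.475 with an estimated correlation).

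Amino acid stress and lipid genes moved in single members. Slc3a2, a subunit of amino acid transporters, fell (-1.82 ± 0.12, adjusted p = 0.00147) and so did Atf4, the transcription factor of the integrated stress response (-1.19 ± 0.10, adjusted p = 0.0024). These were the 2 members called of 24 in that list (adjusted over the list alone, 3 fell). In the cholesterol list 3 of 20 fell, Hmgcs1 (-0.53 ± 0.10) and Pmvk (-0.45 ± 0.09) among them, while adjusted over the list alone 4 fell and 1 rose. Srebf1, a driver of lipogenesis, rose (0.73 ± 0.15, adjusted p = 0.0422), as the only called member of 20 (1 rose and 1 fell adjusted over the list alone). Dgat1 (-0.58 ± 0.10), of triglyceride synthesis, was the only called member of 19 adipocyte genes (1 fell adjusted over the list alone). Pfkfb3, a glycolytic regulator, fell from 1987 ± 51.4 to 918 ± 11.4 CPM (adjusted p = 0.00337), as the only called member of 19 glucose genes (1 fell adjusted over the list alone). In the list of futile cycles Pck1, of glycerol synthesis, fell (-0.79 ± 0.15) and the calcium channel Ryr2 rose (2.06 ± 0.40), with the same counts adjusted over the list alone.

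Thermogenic genes gave no call in this comparison: 0 of 27 passed, also adjusted over the list alone, and their median log2 fold change was -0.16. The 42 nuclear-encoded respiratory chain genes (median 0.00446, which became -0.000622 after median-of-ratios scaling, with a set test towards lower values) and the 23 genes of fatty acid oxidation (-0.06) gave 0 calls likewise, and 0 of 13 genes encoded in mitochondria were in the table. Aplnr, the apelin receptor of endothelial cells, rose from 10.6 ± 2.92 to 71.5 ± 20.97 CPM (adjusted p = 0.0198), and so did the endothelial genes Erg (0.64 ± 0.13) and Tek (0.45 ± 0.10), 2 of 13 (2 also adjusted over the list alone). Plk2 (0.97 ± 0.18) and Bbc3 (0.93 ± 0.17) rose among 18 p53 genes (5 rose and 1 fell adjusted over the list alone). Single members rose in the interferon list (Rsad2, 1.34 ± 0.19, of 21), the macrophage list (Cx3cr1, 2.09 ± 0.40, of 18) and the nerve list (S100b, 0.54 ± 0.12, of 9), and Syvn1 (-0.60 ± 0.10) fell among 18 genes of the unfolded protein response. Adjusted over each list alone, these 4 lists gave 1, 1, 1 and, for the last, 1 rise with 1 fall. Hoxa2 (2.38 ± 0.30), Sgol2a (2.40 ± 0.46) and Ttc30a1 (2.30 ± 0.31) completed the largest rises under the rule for named genes.

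Skeletal muscle transcripts were present in the brown wild type libraries and near 0 in the 4 transgenic ones. Mean log2 CPM of the 19 muscle genes was 6.73 and 5.54 in wild type, and between -0.16 and -0.07 with the transgene. Muscle RNA thus coincided with genotype. Differences from wild type in brown adipose, in muscle and in other genes, are therefore not separated from the tissue dissected. Pvalb (at least 575-fold lower, adjusted p = 0.00229), Actn3 (at least 549.9-fold) and Myh7 (at least 267-fold) were at 0 with 1 copy, as were Eef1a2 (at least 194-fold) and Myoz1 (at least 181-fold), while Tnnt3 fell from 136 ± 64.4 to 0.0293 ± 0.0414 CPM. With Tnnt1 (-6.18 ± 0.52) and Casq1 (-7.99 ± 0.65), 14 of 19 muscle genes fell and 19 did adjusted over the list alone (adjusted p = 4.32e-99, and adjusted p = 0.247 with an estimated correlation). Their median was -9.89, and -9.10 with the 7 genes at 0 set at their bounds. Lymphocyte genes had a median of 0.90 with 0 of 10 called (adjusted p = 0.0176, and adjusted p = 0.659 with an estimated correlation).

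In all, 546 of 13414 genes passed with 1 copy, 204 higher and 342 lower. Of the lower genes 48 were marked as muscle transcripts from a white library, and 469 calls were left without the marked genes. The mark covered 14 of the 19 genes of the muscle list, so muscle genes may remain among those calls. The count depended on single libraries: 26 genes passed without 1-copy replicate 1, 47 without 1-copy replicate 2 and 880 without wild type replicate 2. Dbp, Nfil3, Cry2, Hlf, Slc3a2, Atf4, Pvalb, Myh7 and Tnnt1 passed in all 6 fits that left out 1 library, and every other gene named for this comparison failed in at least 1 of them. Of the 35 named genes, 26 and 23 failed without 1-copy replicates 1 and 2 (adjusted p 0.0692 to 0.333 and 0.0573 to 0.242). Fewer failed without wild type replicates 1 and 2 (13 and 7, up to 0.121 and 0.0791) or 2-copy replicates 1 and 2 (6 each, up to 0.0651 and 0.0659).

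**Figure D2:**
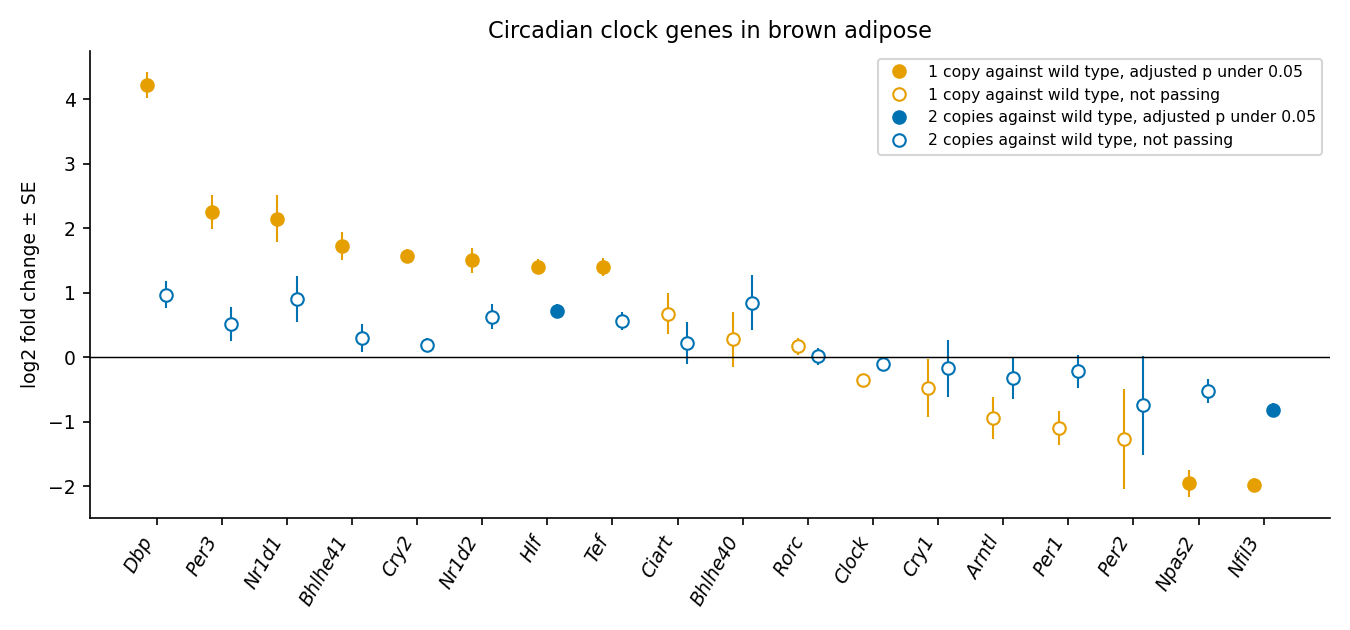
Log2 fold change against wild type (vertical axis, ± SE) of the 18 clock genes in brown adipose with 1 copy and with 2 copies, filled where the adjusted p passed. Dbp stood at 4.22 with 1 copy and 0.97 with 2 copies, and Nfil3 at -1.99 and -0.81.

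Brown adipose with 2 copies was compared with wild type in the same fit. Tbc1d9 had the smallest adjusted p among the genes that rose (0.00802), and the other largest rises under the rule for named genes were Alox12 (2.17 ± 0.27), Fhdc1 (1.68 ± 0.23), Tjp3 (1.61 ± 0.24), Ttc25 (1.57 ± 0.23) and Pde7b (1.39 ± 0.20). The matrix genes Mmp2, a collagen-degrading protease (-1.10 ± 0.16, adjusted p = 0.0316), and Col6a3 (-0.95 ± 0.16, adjusted p = 0.0402) fell, 2 of 19, with 7 falls adjusted over the list alone (adjusted p = 2.5e-05, and adjusted p = 0.652 with an estimated correlation). The brown wild type libraries also held muscle transcripts, so these and the other falls are not separated from that tissue. Thermogenic genes had a median of 0.22 with 0 of 27 called, while 4 rose and 1 fell adjusted over the list alone (adjusted p = 0.00265, and adjusted p = 0.261 with an estimated correlation). The respiratory chain list had a median of -0.19, 1 called fall of 42 in Ndufs7 (-0.52 ± 0.09) and 4 falls adjusted over the list alone (adjusted p = 7.6e-05, and adjusted p = 0.652 with an estimated correlation). Of the clock genes Hlf rose (0.71 ± 0.11) and Nfil3 fell (-0.81 ± 0.10), with 4 rises and 1 fall adjusted over the list alone (adjusted p = 0.139). As a list, Ucp1 and its neighbours had 1 called rise of 3 with each dose, and 1 and 2 rises adjusted over the list alone (adjusted p = 0.258 with 1 copy and 7.62e-09 with 2 copies, the latter adjusted p = 0.144 with an estimated correlation).

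The remaining lists discussed here held at most 1 called gene with 2 copies. Kdr, the VEGF receptor, rose (0.66 ± 0.11) as the called member of 13 endothelial genes (4 adjusted over the list alone; adjusted p = 0.00173, and adjusted p = 0.652 with an estimated correlation). Alpl, a phosphatase of the creatine cycle, rose (0.94 ± 0.16; 2 rises and 2 falls adjusted over the list alone), and Syvn1 fell again (-0.68 ± 0.10; 1 rise and 1 fall adjusted over the list alone). Cholesterol genes had a median of 0.34 and 0 of 20 called (3 rises and 1 fall adjusted over the list alone; adjusted p = 0.00212, and adjusted p = 0.642 with an estimated correlation). Medians were -0.39 for macrophage genes, 0.72 for lymphocyte genes and -0.68 for immediate early genes, with 0 called in each, also adjusted over the list alone (adjusted p = 0.0186, 0.0279 and 0.0292, and adjusted p = 0.652 with an estimated correlation in all 3).

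Muscle transcripts were again the largest falls, with Pvalb at least 626-fold, Myh7 at least 290.2-fold and Apobec2 at least 133-fold lower than in wild type. Ttn was at 0.0299 ± 0.0423 against 113 ± 59.6 CPM, Tnnt3 at 0.0559 ± 0.0056 against 136 ± 64.4 CPM and Atp2a1 at 0.21 ± 0.296 against 380.0 ± 231 CPM. Tnnt1 (-5.90 ± 0.50) and Casq1 (-8.10 ± 0.65) were among the 12 of 19 muscle list genes that fell (19 adjusted over the list alone; adjusted p = 1.58e-120, and adjusted p = 0.144 with an estimated correlation; median -9.62, or -9.01 with the genes at 0 set at their bounds). In all 173 genes passed, 63 higher and 110 lower. Of the lower ones 36 carried the muscle mark, and 86 genes passed without the marked genes. Muscle genes may remain among these too, as the mark covered 14 of the 19 genes of the muscle list. Leaving out single libraries gave 21 and 23 calls without either 1-copy replicate, 8 and 20 without 2-copy replicates 1 and 2, and 334 without wild type replicate 1. Of the 22 called genes named here, Tbc1d9, Pvalb and Myh7 passed in all 6 such fits. Without 2-copy replicates 1 and 2, 19 and 18 failed (adjusted p up to 0.147 and 0.155), without either 1-copy replicate 14 (up to 0.119), and without wild type replicates 1 and 2, 2 and 5 (up to 0.0579 and 0.106).

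Between brown libraries with 2 copies and with 1 copy, 262 genes differed, 167 higher and 95 lower. Mfsd2a, a lipid transporter, rose from 1.54 ± 0.06 to 86.1 ± 29.4 CPM (adjusted p = 0.00563). Elovl3, an elongase of very long fatty acids that marks active brown fat, rose from 48.3 ± 9.73 to 359 ± 105 CPM (adjusted p = 0.0408). Lrrc52 (4.32 ± 0.60), Dhrs9 (2.32 ± 0.19) and Hcn2 (2.18 ± 0.26) were the other largest rises under the rule for named genes, and the largest falls were Dbp (-3.25 ± 0.19, adjusted p = 0.00168), Snhg11 (-2.68 ± 0.30), Myc (-2.23 ± 0.29), Ptgds (-1.88 ± 0.24) and Sox4 (-1.78 ± 0.25). In the clock list 6 fell and 2 rose of 18, and 8 fell and 4 rose adjusted over the list alone. The set test gave adjusted p = 6.2e-05 for the clock list (adjusted p = 0.44 with an estimated correlation). For the cholesterol and thermogenic lists it gave adjusted p = 1.01e-07 and 8.3e-06 (adjusted p = 0.241 with an estimated correlation for both). Cholesterol genes had a median of 0.56 with 4 of 20 higher (10 higher and 1 lower adjusted over the list alone), and among thermogenic genes Elovl3 was the only call of 27 (11 adjusted over the list alone). Lower as sets, with 0 calls each, were macrophage genes (median -0.51, adjusted p = 2.42e-05, and adjusted p = 0.552 with an estimated correlation) and respiratory chain genes (median -0.16, adjusted p = 0.000949, and adjusted p = 0.64 with an estimated correlation). Muscle genes gave 0 calls of 19. Calls numbered 7 and 10 without 1-copy replicates 1 and 2, and 88 and 29 without 2-copy replicates 1 and 2. They numbered 800 and 812 without wild type replicates 1 and 2. Dbp and Dhrs9 passed in all 6 fits. Of the 10 genes named by the rule, 8 failed without either 1-copy replicate (adjusted p up to 0.174 and 0.239), and 4 and 5 without 2-copy replicates 1 and 2 (up to 0.0632 and 0.0982).

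Changes shared by the 2 doses in brown adipose were counted against what the common wild type libraries give by themselves. With 1 copy and with 2 copies 16 genes were higher and 76 lower. Independent lists of these sizes would share 0.958 and 2.8, and unchanged groups simulated against the same controls shared 0.7 and 0.4 (means of 20 simulations). Few genes are called in unchanged groups, so these low counts do not measure the overlap that shared controls give to longer lists. The fold changes of the 2 doses correlated across genes with r = 0.761 (0.484 simulated; genes are not independent replicates), and their covariance of 0.594 exceeded the simulated 0.058 by 0.536. Muscle RNA in the wild type libraries feeds these values, as 36 of the 76 shared falls carried the muscle mark. The mark covered 14 of the 19 genes of the muscle list, so values without the marked genes may still hold muscle RNA. Without the marked genes and with p adjusted again, a count added after the data were seen, 10 genes were higher and 26 lower with both doses, r was 0.59 (0.484 simulated) and the covariance 0.258 (0.0568 simulated). The 2 wild type libraries were not split between the doses, which would leave 1 for each, so part of the excess may come from the shared controls.

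White adipose with 1 copy and with 2 copies was compared with wild type next. Lymphocyte genes were at a high level in all 4 transgenic white libraries (mean log2 CPM 7.38 to 7.58) and near 0 in the 2 wild type ones (0.18 and 0.37). Cd79b, part of the B cell receptor, rose from 1.49 ± 0.08 to 225 ± 5.19 CPM with 1 copy and 236 ± 0.37 CPM with 2 copies. Cd8b1, of cytotoxic T cells, rose from 0.32 ± 0.002 to 136 ± 2.93 and 174 ± 9.69 CPM (adjusted p = 1.42e-06 and 1.28e-06 for both genes). All 19 lymphocyte genes tested rose with each dose, also adjusted over the list alone, with medians of 8.21 and 8.40 (adjusted p = 8.93e-134 and 7.31e-103; adjusted p = 0.0214 and 0.0505 with an estimated correlation). Adipocyte genes fell, 18 of 19 with 1 copy and 19 of 19 with 2 copies, by medians of -0.92 and -2.08.

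Glycam1, a sialomucin of the high endothelial venules through which lymphocytes enter lymph nodes, rose from 0.0268 ± 0.0379 to 1433 ± 177 and 1306 ± 97.3 CPM (adjusted p = 2.36e-06 and 2.15e-06). The B cell factor Pax5 was at 54.3 ± 5.43 and 59.9 ± 7.69 CPM, at least 675-fold and 755-fold above wild type, where it was at 0. Dapl1 (at least 299-fold and 407-fold) and the chemokine receptor Ccr6 (at least 215.1-fold and 214.5-fold) were also at 0 in wild type, as were Pcdh15 for 1 copy (at least 112-fold) and Dscaml1 for 2 copies (at least 173-fold). Cr2, a complement receptor of B cells and follicular dendritic cells, rose to 119 ± 21.3 CPM with 1 copy, and Nsg2 to 83.3 ± 1.38 CPM with 2 copies. The integrin gene Itgax, of dendritic cells, rose (3.16 ± 0.29 and 3.39 ± 0.30), and so did Cx3cr1 (1.78 ± 0.23 and 1.72 ± 0.23). In the macrophage list as a whole 4 of 19 rose with each dose while 8 fell with 1 copy and 6 with 2 copies (4 rises with 9 and 6 falls adjusted over the list alone; adjusted p = 0.269 and 0.688).

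**Figure D3:**
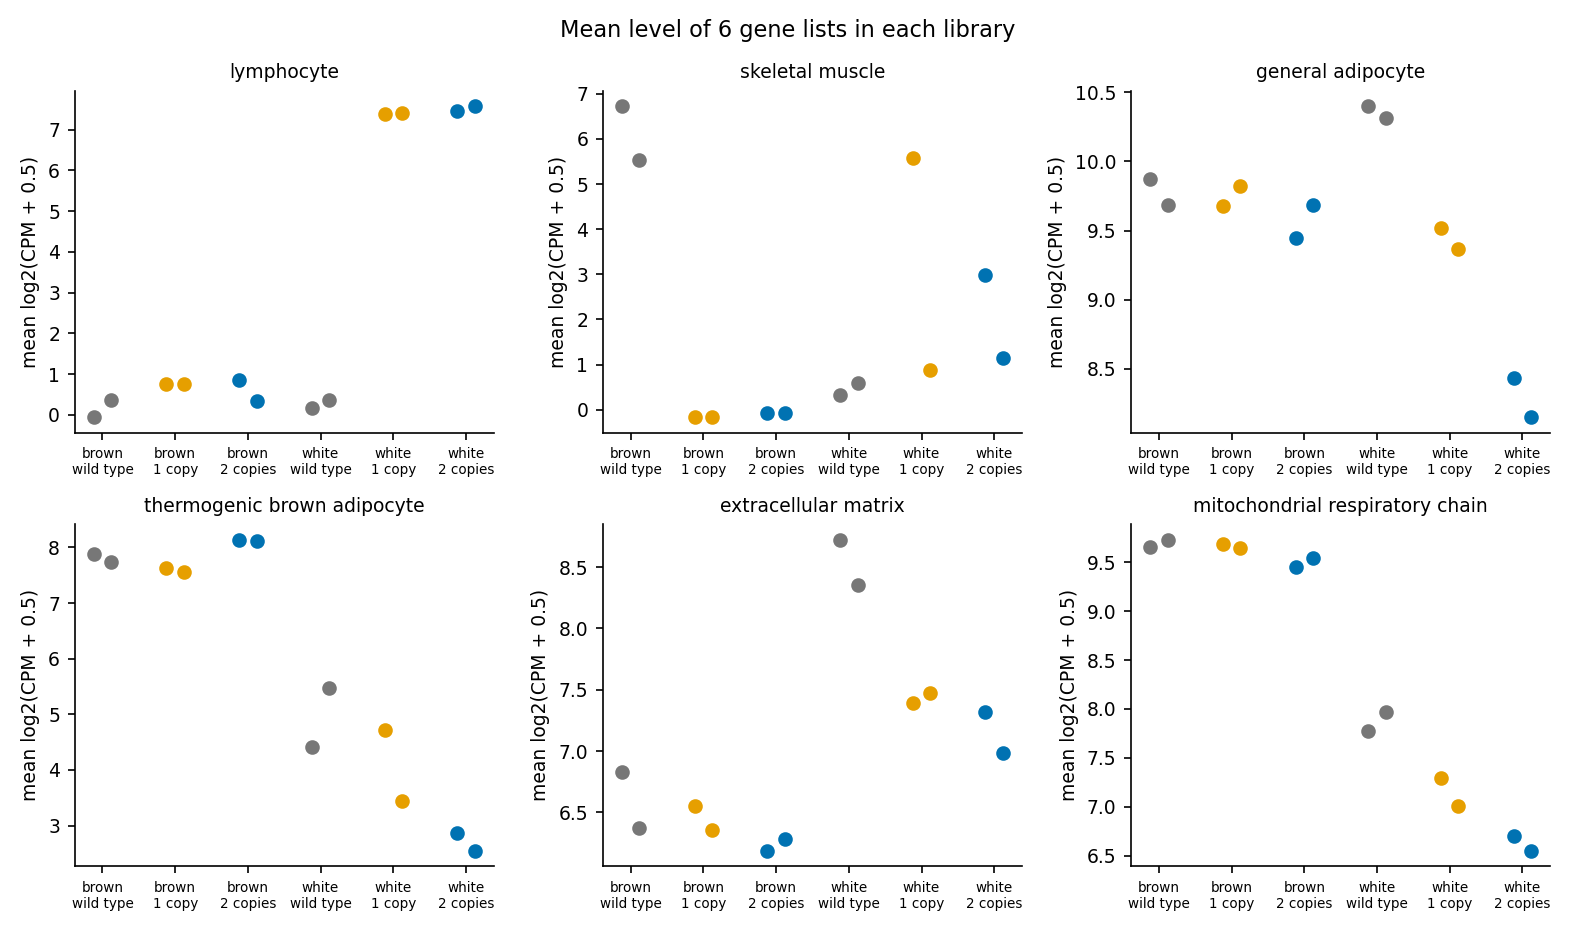
Mean log2(CPM + 0.5) of 6 gene lists (vertical axes) in each of the 12 libraries, by tissue and genotype. Lymphocyte genes lay between 7.38 and 7.58 in the 4 transgenic white libraries, and muscle genes at 6.73 and 5.54 in the brown wild type libraries and 5.58 in 1 white library with 1 copy.

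Adipocyte programmes were lower in the transgenic white libraries, which also held the higher lymphocyte transcripts. Aqp7, the glycerol channel of adipocytes, changed by -0.78 ± 0.13 with 1 copy and -2.08 ± 0.13 with 2 copies on the log2 scale, and the adipogenic factor Cebpa by -0.90 ± 0.13 and -2.13 ± 0.14 (adjusted p = 0.00258 and 8.28e-05). The adipocyte list fell by the same numbers adjusted over the list alone (adjusted p = 6.01e-05 and 1.38e-11; adjusted p = 0.821 and 0.467 with an estimated correlation). Lipogenic genes fell, 17 and 20 of 20 (19 and 20 adjusted over the list alone; medians -0.96 and -2.27; adjusted p = 0.000153 and 4.82e-09, and adjusted p = 0.821 and 0.489 with an estimated correlation). The glucose-sensing factor Mlxipl was at -1.51 ± 0.16 and -2.42 ± 0.17 and Pnpla3 at -1.21 ± 0.18 and -2.57 ± 0.18. In fatty acid oxidation 18 and 21 of 23 fell, the same adjusted over the list alone (medians -0.86 and -1.70; adjusted p = 0.000699 and 1.03e-07, and adjusted p = 0.889 and 0.642 with an estimated correlation). Examples were Cpt2 (-0.82 ± 0.10 and -1.74 ± 0.10) and Acsl1 (-1.01 ± 0.19 and -2.003 ± 0.198). Respiratory chain genes fell, 41 and 42 of 42, again the same adjusted over the list alone (medians -0.69 and -1.18; adjusted p = 1.2e-08 and 4.55e-14, and adjusted p = 0.889 and 0.642 with an estimated correlation). Ndufb3 was at -0.85 ± 0.09 and -1.19 ± 0.09 and Ndufa8 at -0.57 ± 0.08 and -0.95 ± 0.08.

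Of 25 thermogenic genes 6 fell with 1 copy and 16 with 2 copies (3 and 16 adjusted over the list alone; medians -0.95 and -2.49). The set test gave adjusted p = 0.029 and 0.000237, and adjusted p = 0.898 and 0.757 with an estimated correlation. Mean log2 CPM of the list was 4.711 and 3.441 in 1-copy replicates 1 and 2, against 4.418 and 5.475 in wild type replicates 1 and 2. Libraries with 1 copy thus overlapped with wild type. Between 2 copies and 1 copy 2 of the 25 were lower (9 adjusted over the list alone; adjusted p = 4.13e-10, and adjusted p = 0.437 with an estimated correlation). Prdm16 (-0.78 ± 0.11 and -1.54 ± 0.11) and Ebf2 (-1.01 ± 0.18 and -1.84 ± 0.19), which set the identity of brown and beige adipocytes, fell with both doses. General adipocyte genes fell by medians of -0.92 and -2.08, so the falls of Prdm16 and Ebf2 are not separated from a lower share of adipocyte RNA. The beige fat markers Cidea, from 135 ± 75.1 to 5.39 ± 1.36 CPM (adjusted p = 0.00439), Otop1, from 37.6 ± 17.5 to 1.52 ± 0.22 CPM (adjusted p = 0.000504), and Cox7a1 (-3.89 ± 0.74) were among the 6 largest falls with 2 copies under the rule for named genes, with Zbtb16 (-3.73 ± 0.47), Nnat (-3.64 ± 0.55) and Esrrb (-3.83 ± 1.09). Wild type values of these genes were uneven, as the SD of Cidea shows, and Ucp1 was at 16.6 and 212 CPM of the totals in the 2 wild type libraries. Under the same rule the largest falls with 1 copy were Clca1 (70.2 ± 6.41 to 1.67 ± 1.73 CPM, adjusted p = 0.0034), Krt6a (-5.35 ± 1.13), Esrrb (-5.29 ± 1.26), Mmd2 (-5.12 ± 1.47), Greb1 (-4.51 ± 1.38) and Olfm4 (-4.24 ± 0.92).

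Most lists of other tissue compartments fell too, while cell cycle genes rose. With 1 copy medians were -1.34 for nerve, -0.93 for macrophage, -0.68 for progenitor and -0.36 for endothelial genes, beside -0.92 for adipocyte genes. The epithelial median was -0.46. Whether added lymphoid RNA lowered the share of all other RNA against wild type was not tested, so these falls are not separated from such a dilution. Matrix genes fell, 19 and 18 of 21, while 2 and 1 rose, the same adjusted over the list alone (medians -1.24 and -1.67; adjusted p = 9.18e-07 and 1.5e-07, and adjusted p = 0.821 and 0.619 with an estimated correlation). Examples are Dpt (-0.99 ± 0.10 and -1.70 ± 0.11) and elastin, Eln (-1.60 ± 0.10 and -1.40 ± 0.10). The nerve and Schwann cell list fell in 8 of 9 members with each dose (9 and 8 adjusted over the list alone; adjusted p = 4.01e-05 and 0.000237, and adjusted p = 0.229 and 0.3 with an estimated correlation). Its members that fell included Prx (-1.75 ± 0.14 and -1.91 ± 0.14). Of 13 endothelial genes 7 fell and 2 rose with 1 copy and 10 fell and 1 rose with 2 copies (8 with 2, and 11 with 1, adjusted over the list alone; adjusted p = 0.0982 and 0.00151, the latter adjusted p = 0.3 with an estimated correlation). Tek was at -0.64 ± 0.07 and -1.17 ± 0.08 and Cdh5 at -0.48 ± 0.08 and -1.11 ± 0.09. Cell cycle genes rose, 9 and 18 of 22 (8 and 19 adjusted over the list alone; medians 0.52 and 1.01; adjusted p = 0.175 and 0.00575, the latter adjusted p = 0.846 with an estimated correlation). These included the helicase subunits Mcm2 (1.201 ± 0.176 and 1.527 ± 0.177) and Mcm6 (0.80 ± 0.12 and 1.28 ± 0.12). The cell cycle rises are not separated from the lymphoid RNA of the transgenic libraries. The list of progenitor markers went both ways (3 rose with each dose, 8 and 6 of 13 fell; 3 rose with 9 and 6 falls adjusted over the list alone; adjusted p = 0.309 and 0.776). Its members that rose included Icam1 (2.22 ± 0.10 and 2.47 ± 0.10) and Thy1 (1.45 ± 0.14 and 1.86 ± 0.14), which lymphoid cells also express. Muscle genes were at a mean log2 CPM of 5.58 in 1-copy replicate 1, 2.99 in 2-copy replicate 1 and at most 1.16 in the 4 other white libraries. Tnnt1 (2.06 ± 0.52 and 2.18 ± 0.52) and, with 2 copies, Myh7 (4.04 ± 0.91; 1 copy 2.65 ± 0.98, adjusted p = 0.0627) rose among 3 and 2 calls of 19 (0 adjusted over the list alone).

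Metabolic lists outside fat storage held more falls than rises. Neither the falls nor the rises are separated from the lymphoid RNA of the transgenic libraries. Glycolysis and glucose uptake genes fell in 14 and 16 of 19 and rose in 2, the same adjusted over the list alone (medians -0.75 and -1.24; adjusted p = 0.00656 and 0.000183, and adjusted p = 0.889 and 0.644 with an estimated correlation). Pgam1 was at -0.81 ± 0.10 and -1.25 ± 0.10, and hexokinase 1, Hk1, was higher (0.59 ± 0.08 and 0.80 ± 0.08). Creatine and other futile cycle genes fell in 5 and 8 of 9 and rose in 1 (6 and 8 falls adjusted over the list alone; adjusted p = 0.105 and 0.051). Gamt (-0.61 ± 0.14 and -1.40 ± 0.15) and Ckb (-0.68 ± 0.16 and -1.01 ± 0.16), both of creatine metabolism, were among them. Of 20 cholesterol genes 9 and 14 fell and 3 rose, the same adjusted over the list alone (adjusted p = 0.101 and 0.0182, the latter adjusted p = 0.757 with an estimated correlation). Hmgcs1 was at -1.17 ± 0.15 and -1.64 ± 0.15 and the regulator Srebf2 was higher (0.83 ± 0.08 and 0.88 ± 0.08). All 5 blood genes fell, also adjusted over the list alone (adjusted p = 0.0494 and 0.0816, the former adjusted p = 0.889 with an estimated correlation). The globin genes with identical counts, Hba-a1 and Hba-a2, were at -1.39 ± 0.27 and -1.51 ± 0.27. Of 13 epithelial genes 3 fell with 1 copy, Krt19 (-1.42 ± 0.31) and Krt18 (-1.25 ± 0.28) among them, and 0 with 2 copies, the same adjusted over the list alone (adjusted p = 0.131 and 0.762).

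In all 7951 of 15287 genes passed with 1 copy, 4349 higher and 3602 lower, and 9327 passed with 2 copies, 4904 higher and 4423 lower. Lymphocyte transcripts were in all 4 transgenic libraries, so no count without them could be made, and 5270 and 5113 genes passed for 1 copy without 1-copy replicates 1 and 2. Both doses shared 4199 higher and 3234 lower genes, where independent lists would share 1400 and 1040. Unchanged groups simulated against the same controls shared 0.4 and 0.1. Few genes are called in unchanged groups, so these low counts do not measure the overlap that shared controls give to lists this long. The fold changes of the 2 doses correlated across genes with r = 0.949 (0.51 simulated) and the covariance of 2.26 exceeded the simulated 0.0758 by 2.18. Lymphocyte transcripts in all 4 transgenic libraries feed these values. The wild type libraries were not split here either, so part of this may come from the shared controls.

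Some of the genes named for white adipose lost their call without 1 library. Of 59 named called genes, 12 and 11 failed for 1 copy without 1-copy replicates 1 and 2, 7 and 6 without wild type replicates 1 and 2, and 1 without either 2-copy replicate. With 1 copy these were Tbc1d9 (adjusted p = 0.0627 and 0.0686 without 1-copy replicates 1 and 2), Ckb (0.0684 and 0.0668 without the same), Esrrb (0.0935 and 0.0885), Olfm4 (0.0559 without 1-copy replicate 1), Gamt (0.0878 without it) and Acsl1 (0.0528 without 1-copy replicate 2). Krt6a failed without wild type replicates 1 and 2 and 1-copy replicate 1 (0.0713, 0.0521 and 0.0691), and Mmd2 and Greb1 without any of the 4 libraries compared (up to 0.189 and 0.155). Krt19 failed without wild type replicate 2 (0.082), Krt18 without either wild type replicate (0.064 and 0.0789), Hba-a1 and Hba-a2 without wild type replicate 1 or 1-copy replicate 2 (0.0533 and 0.0554), and Tnnt1 without wild type replicate 2 or either 1-copy replicate (0.0679, 0.0914 and 0.0534). With 2 copies Elmod2 failed without wild type replicate 1 (0.0508), Tnnt1 without 2-copy replicate 1 (0.062), and Esrrb without wild type replicate 1 or either 2-copy replicate (0.0885, 0.0687 and 0.131). Dnajb9, Xbp1, Irf9 and Xist, whose values are among the other observations, also failed in at least 1 such fit.

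**Figure D4:**
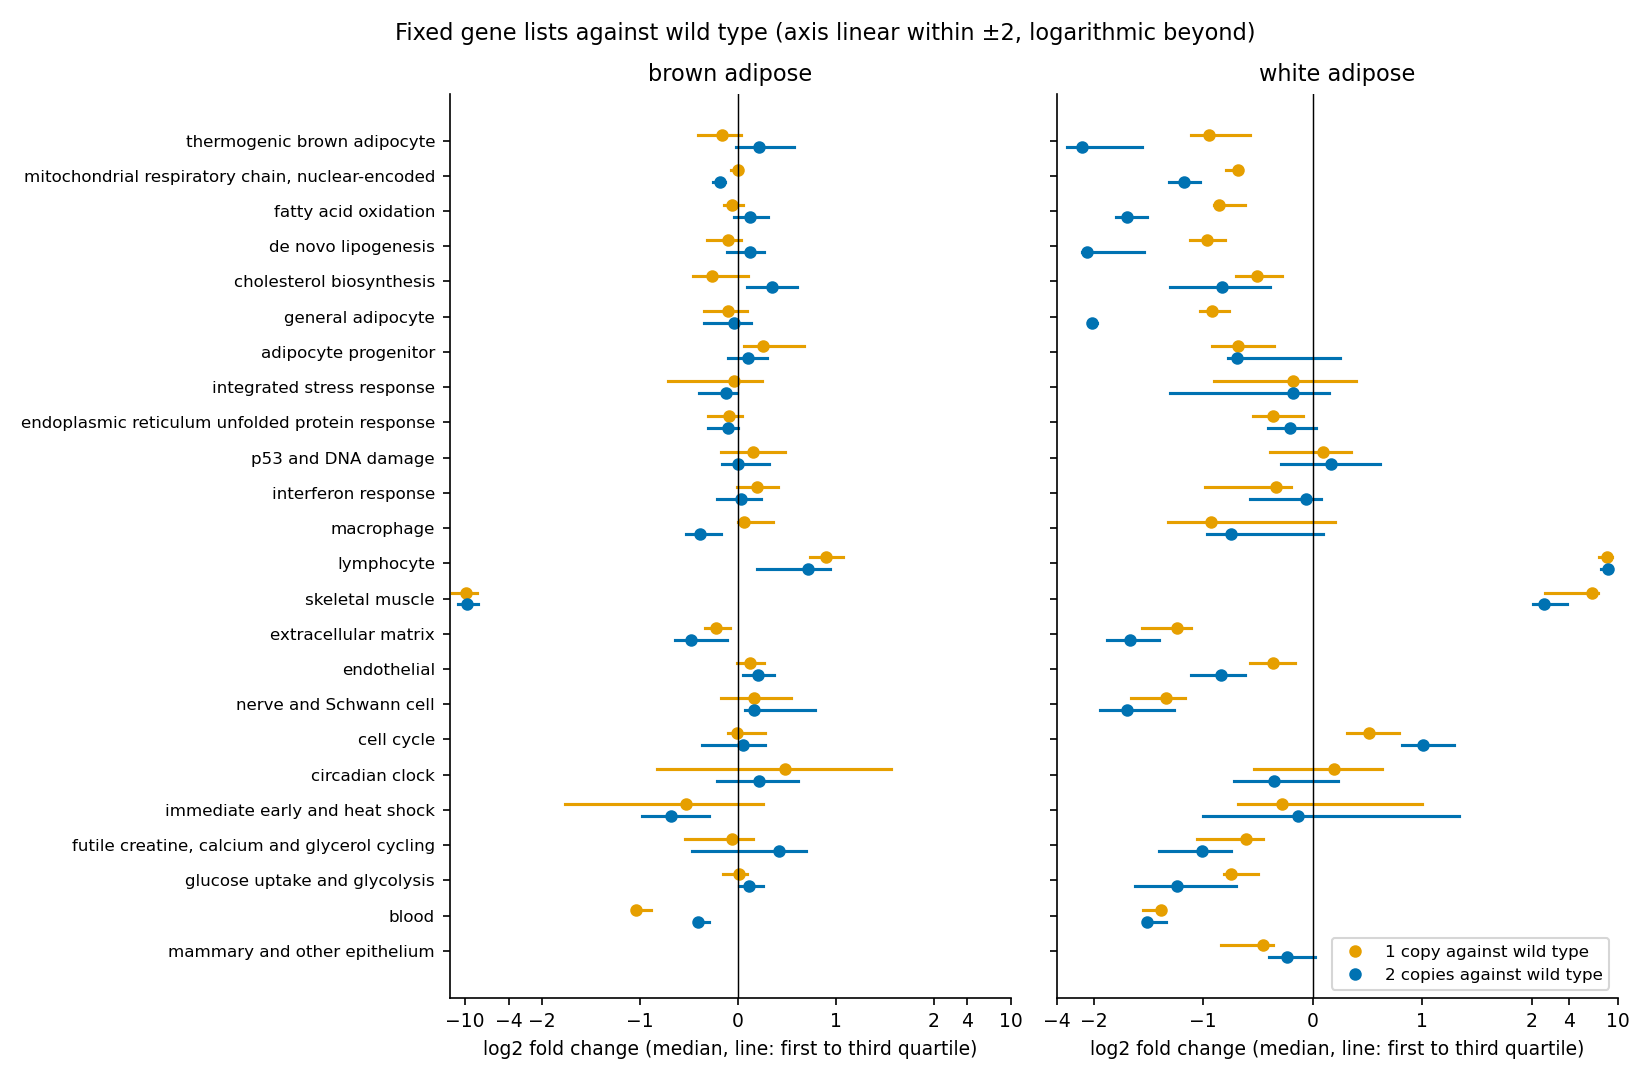
Median log2 fold change against wild type (horizontal axis, linear within 2 of 0 and logarithmic beyond, lines from the first to the third quartile) of the fixed gene lists in brown and white adipose, for 1 copy and 2 copies. In white adipose lymphocyte genes lay at 8.21 and 8.40 and adipocyte genes at -0.92 and -2.08, and in brown adipose muscle genes lay at -9.89 and -9.62.

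White adipose with 2 copies was also compared with 1 copy. Adipocyte genes were lower with 2 copies, 8 of 19 (16 adjusted over the list alone), with a median of -1.23, while 0 of 19 lymphocyte genes passed (2 adjusted over the list alone) at a median of 0.14. The set test gave adjusted p = 8.49e-33 for adipocyte genes (adjusted p = 0.261 with an estimated correlation) and 0.0126 for lymphocyte genes (adjusted p = 0.525 with an estimated correlation). Under the rule for named genes the largest falls were Otop1 (-2.98 ± 0.43, adjusted p = 0.0443), Sncg (-2.38 ± 0.23, adjusted p = 0.0253), Gys2, liver-type glycogen synthase (-2.10 ± 0.28), Lctl (-2.05 ± 0.27) and Timp4 (-1.94 ± 0.23). Only 5 of the 285 called genes were higher with 2 copies: Slc5a5, the iodide transporter, from 58.8 ± 6.32 to 210.4 ± 68.3 CPM, Anxa3 (0.91 ± 0.12), S100a6 (0.84 ± 0.14), Basp1 (0.76 ± 0.11) and the chemokine Ccl22 (0.71 ± 0.11). Without any of the 4 transgenic libraries in turn, edgeR called 0 genes, and without wild type replicates 1 and 2 it called 579 and 586, of which 57 and 61 were higher. At an unadjusted p under 0.05 the full set of libraries gave 2873 genes, and DESeq2 called 1230 after adjustment, 205 of them higher. In the fit of all 12 libraries 30 of 780 were higher. All 10 genes named here failed without any of those 4 libraries (adjusted p up to 0.341), and Slc5a5 and S100a6 also without either wild type replicate (up to 0.0569).

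The 2 depots were compared in wild type mice as a check of tissue identity, in a fit of all 12 libraries. Brown fat had 8122 ± 1332 CPM of Ucp1 against 103 ± 124 in white (log2 fold change 6.31 ± 1.85, adjusted p = 0.0202) and 2408 ± 89.2 CPM of Cidea against 112 ± 62.9 (adjusted p = 0.000259). Lep, the satiety hormone of white fat, was lower in brown (-3.77 ± 0.96, adjusted p = 0.011). The patterning gene Zic1 was at 0 in white and at least 139-fold higher in brown (adjusted p = 4.05e-05), and Hoxc10 was at 0 in brown and at least 391-fold lower there (adjusted p = 1.92e-06). Ucp1 did not pass without white wild type replicate 1 (adjusted p = 0.092), nor Lep without brown wild type replicates 1 and 2 (0.0509 and 0.0678). In all 9507 of 15559 genes differed, 4505 higher in brown and 5002 lower. Part of this count may come from muscle RNA. Mean log2 CPM of the muscle list was 6.73 and 5.54 in the brown wild type libraries and 0.34 and 0.59 in the white ones.

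Whether the difference from wild type was unequal in the 2 depots was tested as an interaction, the effect in brown minus that in white. With 1 copy 5076 genes differed, 2150 with a higher effect in brown and 2926 with a lower one. With 2 copies 6568 differed, 3199 higher and 3369 lower. The test does not separate the transgene from the tissue dissected, since lymphocyte transcripts were high in the transgenic white libraries only, and all 19 lymphocyte genes had a lower effect in brown with each dose (medians -7.52 and -7.78). Otop1 (5.12 ± 0.50, adjusted p = 0.00011), Elovl3 (5.09 ± 1.23), Cidea (4.47 ± 0.77, adjusted p = 0.00231), Cpn2 (5.15 ± 1.36) and Ucp1 (9.12 ± 2.88, adjusted p = 0.038) had the largest differences towards brown with 2 copies under the rule for named genes. Their log2 fold changes in white fat ran from -8.54 for Ucp1 to -2.94 for Elovl3. With 1 copy these were Faim2 (adjusted p = 0.0315), Esrrb (5.47 ± 1.35), Gldn (4.79 ± 1.17), the patterning gene Hoxa9 (3.94 ± 0.52, adjusted p = 0.000541) and Nxph3 (3.92 ± 1.12). The largest differences towards white under that rule were muscle genes, which brown wild type libraries and 1 or more transgenic white libraries contained, namely Ckm, Pvalb, Tnni2, Actn3 and Atp2a1 for 1 copy (adjusted p = 0.0138 to 0.0498) and Ttn, Tnni2, Cox6a2, Myh7 and Cacna1s for 2 copies (adjusted p = 0.000172 to 0.0371). Most of them were at 0 in at least 1 group, so no fold is given. Hoxa9, Otop1, Cidea, Ttn, Cox6a2, Cacna1s and, for 2 copies, Myh7 passed in all 12 fits that left out 1 library, and the other genes named here failed in at least 1. Each of Faim2, Esrrb, Gldn, Nxph3, Ckm, Pvalb, Tnni2, Actn3 and Atp2a1 failed for 1 copy without 1 or more of the 8 libraries compared, with the highest adjusted p for Ckm without white 1-copy replicate 1 (0.662). For 2 copies Ucp1 failed without 9 of the 12 libraries (up to 0.149 without white 2-copy replicate 2), Cpn2 and Elovl3 without white wild type replicate 2 (0.0831 and 0.0776) or either white 2-copy replicate, and Tnni2 without any of the 8 libraries compared (up to 0.149). Median-of-ratios scaling moved the median of all genes by 0.139 and 0.119 (log2) in the 2 interactions and turned the majority in both, to 3068 higher and 2401 lower genes for 1 copy (56.1% higher against 42.4%) and 3815 higher and 2873 lower genes for 2 copies (57% higher against 48.7%).

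Chromosomal position was examined because an inserted transgene can alter its neighbours. Called genes with 2 copies did not concentrate in any of 521 windows of 5 Mb in brown or 527 in white adipose by the hypergeometric test (0 windows called; the smallest adjusted p was 1 in brown and 0.43 in white, for chromosome 11 from 105000001 to 110000000, where 43 of 53 tested genes were called). In brown adipose the window with the smallest unadjusted p (0.00346) was on chromosome 11 from 90000001 to 95000000, with 3 of 24 genes called. By chromosome, the smallest adjusted p in a one-sided Fisher's exact test was 0.446 in brown and 0.145 in white adipose. With 9327 of 15287 genes called in white adipose, a window could hardly stand out there. Even a window with 13 of 13 tested genes called had an adjusted p of 0.43 by the hypergeometric test. In brown adipose 173 of 13414 genes were called, so a change in a few neighbours could be missed.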

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

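The tests of stromal transcripts in white adipose had been set before their results were seen, while the tests on copy number, dilution, cell shares and the clock were chosen only after the results were seen.

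The difference from wild type was unequal between the depots in many genes by the interaction test, 5076 with 1 copy and 6568 with 2 copies. These counts do not separate the transgene from the tissue dissected, since they include all 19 lymphocyte genes, high in the transgenic white libraries only, and 16 and 12 of 19 muscle genes. The genes below are those named for both tissues, or by the rule for the interaction, whose difference (effect in brown minus effect in white, log2) passed. With 1 copy, Esrrb (5.47), Gldn (4.79), Hoxa9 (3.94) and Nxph3 (3.92) had a higher effect in brown, as had Tek (1.09), which rose in brown (0.45) and fell in white adipose (-0.64). Esrrb (0.18, adjusted p = 0.848) and Gldn (1.97, adjusted p = 0.305) did not pass in brown and fell in white adipose (-5.29 and -2.85). Nxph3, not tested in brown, fell in white adipose (-2.41). Hoxa9 rose in brown (3.05, adjusted p = 0.0431) and fell in white adipose (-0.88). Hmgcs1 fell less in brown (-0.53) than in white adipose (-1.17), a difference of 0.65. Faim2 also differed (adjusted p = 0.0315), and a group at 0 rules out a fold for it. With 2 copies, Ucp1 (9.12), Cpn2 (5.15), Otop1 (5.12), Elovl3 (5.09) and Cidea (4.47) had a higher effect in brown, and of these Cpn2 (-4.89), Otop1 (-4.63) and Cidea (-4.65) fell in white adipose. Tbc1d9 rose more in brown than in white adipose with 2 copies, by 0.87 (adjusted p = 0.00581), and so did Elmod2, by 0.96 (adjusted p = 0.0491), although Elmod2 did not pass in brown adipose alone.

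Muscle genes differed in the other direction, with muscle transcripts in the brown wild type libraries and in some transgenic white libraries. With 1 copy these were Atp2a1 (-19.8), Tnnt1 (-8.25) and, with groups at 0 and so without a fold, Ckm (adjusted p = 0.0484), Pvalb (0.0498), Tnni2 (0.0222), Actn3 (0.0365) and Myh7 (0.000818). With 2 copies they were Ttn (-17.56), Tnnt1 (-8.11), Tnni2 (adjusted p = 0.0371), Cox6a2 (0.00108), Myh7 (0.000172) and Cacna1s (0.00617).

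Lymphocyte transcripts were high in the 4 transgenic white libraries and near 0 in both wild type ones. Of 9 genes of lymphoid stroma and high endothelial venules, 8 were tested and all 8 were higher with each dose. Their medians were 5.10 and 5.32, with ranges of 2.99 to 8.24 and 3.30 to 8.32. Means in unsorted wild type tissue ran from 0.0268 (Chst4) to 3.14 CPM (Cxcl13). Among the tested genes Fut7 and Tnfsf11 can also come from T cells, so they do not mark stroma or venules alone. Ccl21a, which has near-identical copies, was at 252 ± 21.6 and 292 ± 23.9 CPM against 1.31 ± 0.181. Lymphocytes scattered without stroma are argued against by the lower median (5.1). A lymphocyte share of the RNA proportional to copies is argued against by the third quartile between 2 copies and 1 copy (0.353, where doubling needs 1). CPM values are shares of the RNA, so this does not decide whether the number of lymphocytes rose in proportion. The same median of 5.1 is what organised lymphoid tissue, such as a lymph node in the dissected piece, would give, so a candidate explanation is that the pieces from wild type and transgenic mice differed in whether they held a node. An effect of the genotype on lymphoid tissue stays open, since genotype and presence coincide in these 6 libraries (1 of 15 placements of 4 libraries, a share of 0.0667).

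Adipocyte transcripts were lower in white adipose with 2 copies than with 1 copy (median -1.23, quartiles -1.33 and -0.883). Dilution by more lymphoid RNA would lower all other RNA alike, but nerve genes (median -0.103, quartiles -0.28 and 0.221) and epithelial genes (0.328, 0.247 and 0.479) lay apart from the adipocyte list, and the lower of their first quartiles lay 0.603 above the third quartile of that list. A smaller share of adipocytes alone would raise the other cell types alike, but the endothelial median of -0.458 (quartiles -0.52 and -0.33) lay -0.599 from the lymphocyte median of 0.142, and the third quartile of the endothelial list under the first quartiles of the lymphocyte and progenitor lists (-0.0409 and -0.053). Medians were 0.231 for progenitor, 0.137 for macrophage, -0.465 for matrix and 0.476 for cell cycle genes. The muscle list moved more than the adipocyte list, with a median of -3.4. Its mean log2 CPM was 5.58 and 0.87 in 1-copy replicates 1 and 2, and 2.99 and 1.16 in 2-copy replicates 1 and 2. Both arguments rest on the spread between the members of a list, since few members were called, 2 of 13 endothelial genes (12 adjusted over the list alone; adjusted p = 2.27e-08, and adjusted p = 0.214 with an estimated correlation) and 0 in the nerve, epithelial, lymphocyte, progenitor and macrophage lists. A loss of fat together with its vessels, or lower expression per adipocyte, stays open, and an effect of the second copy was not tested apart from these. The calls behind this comparison rest on each transgenic library, since 0 genes passed without white 1-copy replicate 1 or 2 or 2-copy replicate 1 or 2 (edgeR; 1462, 2417, 2112 and 1721 at an unadjusted p under 0.05, and 1230 by DESeq2 with all libraries).

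Clock genes were shifted in brown adipose with 1 copy. In the direction of the shift, the 10 called genes had a median of 1.84 with 1 copy, 0.593 with 2 copies, and -1.31 between 2 copies and 1 copy (quartiles -1.43 and -0.953). Choosing genes by the 1-copy libraries that are then measured pushes this value down. With the genes chosen by 1 of the 1-copy replicates and measured with the other, 5 genes each way, the medians were -1.10 and -1.26, and over 14 genes of known phase, chosen without regard to their calls and without Dbp, -0.858 (quartiles -1.34 and -0.49). These values argue against the loss of muscle RNA, which both doses share, as the source of the whole shift. They also argue against an effect that grows with copies. The part of the shift that remained with 2 copies (median 0.593) is not separated from the loss of muscle RNA. Of those 14 genes 12 moved the way Dbp predicts. That count leaves another hour of collection open, since the direction of the list had been seen before the test was written and an effect on the clock would move the genes alike. In brown adipose with 2 copies and in white adipose with 1 copy 12 of 14 also moved that way, against 7 of 14 in white adipose with 2 copies. An effect of the genotype on the clock stays open too, as hours within the morning are not given.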

How the results depend on the processing

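The counts without muscle-marked genes were added after the data were seen, and all other alternatives given here had been fixed before. No paired analysis was possible because the labels give library numbers only and do not say which libraries, if any, came from the same mouse. The alternative with Xist as a covariate was not run, since no library had the Xist and Y-linked reads of the other sex (Xist at 304 CPM or more and each Y-linked gene at 5 reads or fewer in all 12), although Xist differed by genotype in white adipose.

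Among 228 values of named genes, 225 kept their direction and side of the threshold with median-of-ratios scaling (3 ended their call), 225 with the DESeq2 test (3 more passed), and 216 without a filter on low counts (12 ended their call). All 224 values kept with a mean CPM of at least 1 did so too. In the fit of all 12 libraries 174 of 203 did, 27 ended their call and 2 more passed. Against a fold of 1.5, 75 of 203 ended their call, because that test asks for a larger change. Counts of called genes for the interactions and for wild type depots stayed within 1.5 times of the reported ones in every alternative run, and 0 windows were called in any of theirs.

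Counts of called genes in brown adipose moved for 1 copy to 1044 with DESeq2, 1004 with all 12 libraries and 85 against a fold of 1.5, and leaving out 1 library gave 26 to 880. For 2 copies they moved to 683 with DESeq2, 353 without a filter, 28 against a fold of 1.5 and 86 without muscle-marked genes, and leaving out 1 library gave 8 to 334. For 2 copies against 1 copy they moved to 974 with DESeq2, 516 without a filter, 796 with all 12 libraries, 9 against a fold of 1.5 and 694 with the muscle covariate, and leaving out 1 library gave 7 to 812. In white adipose a fold of 1.5 gave 2548 for 1 copy and 4708 for 2 copies, and leaving out 1 library gave 5113 to 7237 for 1 copy. For 2 copies against 1 copy the counts were 1230 with DESeq2, 780 with all 12 libraries, 0 against a fold of 1.5 (edgeR; 654 at an unadjusted p under 0.05) and 65 with the lymphocyte covariate, and leaving out 1 library gave 0 to 586. Apart from the fold threshold, the cause was not tested. With an estimated correlation 0 lists passed in brown adipose for either dose, 1 in white adipose for 1 copy and 0 for 2 copies (3, 10, 10 and 12 with the preset correlation), and leaving out 1 library gave 4 to 9 lists for 1 copy in brown adipose.

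With the muscle list as a covariate in brown adipose, or the lymphocyte list in white adipose, edgeR called 0 genes for either dose against wild type (1452 and 1624 in brown and 1597 and 1608 in white adipose at an unadjusted p under 0.05; DESeq2 without a covariate called 1044, 683, 7974 and 9114). The covariates followed the genotype, with 98.66% and 99.94% of their variance between wild type and transgenic libraries, so these fits extrapolate by construction. Fitted log2 fold changes turned in sign for 16 values of named genes in brown adipose. For 1 copy these were Ucp1 1.40, Tbc1d9 -0.27, Elmod2 -4.18, Sgol2a -5.75, Per3 -2.24, Hmgcs1 0.26, Syvn1 0.18, Plk2 -0.80, Erg -0.58, S100b -0.00761 and Pck1 0.98. For 2 copies they were Elmod2 -3.02, Syvn1 0.0931, Col6a3 1.66, Kdr -0.18 and Hlf -0.19.

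In white adipose 64 values turned, given as fitted log2 fold changes for 1 copy and 2 copies: Pax5 -4.09 and -4.26, Dapl1 -11.57 and -11.59, Ccr6 -1.24 and -1.49, Esrrb 100.1 and 103.2, Ndufb3 0.57 and 0.25, Ndufa8 0.86 and 0.51, Acsl1 4.16 and 3.25, Srebf2 -1.75 and -1.74, Aqp7 4.37 and 3.16, Cebpa 7.34 and 6.25, Dnajb9 12.35 and 12.57, Xbp1 11.21 and 11.38, Btg2 -3.30 and -3.43, Bbc3 -0.46 and -0.24, Itgax -13.86 and -13.93, Dpt 3.02 and 2.38, Eln 4.26 and 4.56, Tek 1.00 and 0.50, Cdh5 1.99 and 1.40, Prx 7.52 and 7.53, Clock 1.76 and 1.72, Npas2 13.48 and 13.49, Junb -9.18 and -8.91, Gamt 3.06 and 2.33, Ckb 13.65 and 13.57, Pgam1 0.94 and 0.52, Hk1 -0.50 and -0.31, Xist -4.78 and -4.78. For 1 copy alone they were Cr2 -6.52, Clca1 1.93, Krt6a 55.92, Mmd2 103, Greb1 98.12, Olfm4 52.42, Cpt2 0.64, and for 2 copies alone Nnat 32.96. White Ucp1 for 1 copy, which did not pass, turned to 1.61 without white wild type replicate 2, and ran from -6.36 to 1.61 over the fits that left out 1 library.

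At these counts and with 2 libraries per group, simulated changes by a fold of 1.5 were recovered in 13% of genes in brown and 7.41% in white adipose. Those runs changed 200 genes each. In white adipose 7951 and 9327 genes passed against wild type, which makes the adjusted threshold easier to reach. The 7.41% therefore does not give the recovery in those 2 comparisons. The 3 transgenic white libraries without Cre reads held 28 Ucp1 reads or fewer, too few to exclude Cre at the ratio of the other libraries.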

Other observations

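The test on chromosome 8 had been set before its result was seen. The sex-linked, stress and white adipose clock values come from the fixed lists.

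In white adipose the stress lists went both ways. The transgenic white libraries also held lymphocyte transcripts, so changes in these lists are not separated from that tissue. Of 25 tested genes of the integrated stress response 6 rose and 8 fell with 1 copy and 5 rose and 11 fell with 2 copies, the same adjusted over the list alone (adjusted p = 0.744 and 0.764). Slc7a11, the cystine transporter, rose from 0.266 ± 0.149 to 22.0 ± 2.95 and 37.0 ± 3.49 CPM, and Mthfd2, of mitochondrial folate metabolism, rose by 1.91 ± 0.14 and 2.44 ± 0.14 (log2). In the unfolded protein response 2 rose and 4 fell of 18 with 1 copy, and 1 rose and 5 fell with 2 copies (1 with 2, and 1 with 3, adjusted over the list alone; adjusted p = 0.151 and 0.395). Dnajb9 (-0.87 ± 0.17 and -0.89 ± 0.17) and Xbp1 (-0.82 ± 0.18 and -0.86 ± 0.18) were among the falls. Dnajb9 failed for 1 copy without 1-copy replicate 2 (adjusted p = 0.056), and Xbp1 for 1 copy without 1-copy replicate 1 (0.0694) and for 2 copies without 2-copy replicate 2 (0.0549).

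Of 18 p53 genes 5 rose and 4 fell with 1 copy and 6 rose and 3 fell with 2 copies, the same adjusted over the list alone (adjusted p = 0.959 and 0.787). Btg2 (1.52 ± 0.13 and 1.47 ± 0.13) and Bbc3 (1.12 ± 0.13 and 1.37 ± 0.13) rose. Like the other white changes in this paragraph, these rises are not separated from the lymphoid RNA of the transgenic libraries. Of 21 interferon genes 2 rose and 1 fell with each dose (2 rose and 0 fell adjusted over the list alone; adjusted p = 0.242 and 0.764), with a rise in Irf9 (0.62 ± 0.13 and 0.82 ± 0.13), which failed for 1 copy without 1-copy replicate 1 (adjusted p = 0.0602). Of 14 immediate early and heat shock genes 5 and 6 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.895 and 0.764), with rises in Ier2 (1.28 ± 0.12 and 1.51 ± 0.12) and Junb (1.30 ± 0.15 and 1.76 ± 0.16). Of 18 clock genes 4 rose and 6 fell with 1 copy and 2 rose and 8 fell with 2 copies, the same adjusted over the list alone (adjusted p = 0.701 and 0.362), with falls in Clock (-0.54 ± 0.09 and -0.62 ± 0.09) and Npas2 (-1.73 ± 0.29 and -1.99 ± 0.29).

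The median, mean and set test of some lists differed in sign. In white adipose with 1 copy the p53 and clock lists had medians of 0.10 and 0.19 with a set test towards lower values, and the integrated stress and immediate early lists had medians of -0.18 and -0.28 with means of 0.04 and 0.02. With 2 copies the immediate early list had a median of -0.14 with a test towards higher values. In white adipose the mean of Ucp1 and its neighbours was below 0 with each dose (-0.06 and -2.33) against medians of 0.38 and 0.67. In brown adipose with 1 copy the glycolysis list had a median of 0.0093 with a test towards lower values and the cell cycle list a median of -0.0135 with a test towards higher ones. With 2 copies the cell cycle list had a median of 0.0532 with a test towards lower values, the futile cycle list a median of 0.42 with a mean of -0.82, and the interferon list 0.03 with -0.02.

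Of the sex-linked genes only Xist was tested. It rose in white adipose by 0.32 ± 0.11 with 1 copy (adjusted p = 0.0452) and 0.41 ± 0.11 with 2 copies (adjusted p = 0.0173). This rise is not separated from the lymphoid RNA of the transgenic white libraries. The 1-copy call was lost without wild type replicate 1, either 1-copy replicate or either 2-copy replicate (adjusted p = 0.108, 0.106, 0.226, 0.0809 and 0.0795), and the 2-copy call without 2-copy replicates 1 and 2 (0.0611 and 0.0814).

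A hypothesis on chromosome 8 was that the transgene carries a segment with Ucp1, Tbc1d9 and Elmod2, so that Tbc1d9 and Elmod2 may rise while other genes nearby would not rise in both tissues. Of 53 other tested genes within 2 Mb of Ucp1, 0 were higher in both tissues with 2 copies (edgeR). In brown adipose 0 of the 53 were called, with log2 fold changes of -0.991 to 0.716, and in white adipose 24 were higher and 13 lower. Of the genes in the segment, Tbc1d9 rose in both tissues, Elmod2 did not pass in brown adipose (1.63, adjusted p = 0.071), and Ucp1 did not pass in brown (0.596, adjusted p = 0.276) or white adipose (-8.54, adjusted p = 0.0756). The white libraries with the transgene also held lymphoid transcripts, so the rises there are not separated from that tissue. The test is also weak, because in brown adipose few genes of any region passed. A segment of chromosome 8 with Ucp1, Tbc1d9 and Elmod2 carried by the transgene therefore stays open, and so does an effect of an insertion near these genes. Reads were not used here, so copies of the genes were not counted.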
